A study of Mus musculus with 8 samples.

How the data were processed

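Receptor libraries were made from thymocytes of C57BL/6 mice, sorted as CCR6, CD127 and TCR beta positive, with a droplet kit for single-cell immune profiling, per the labels' protocols. The authors deposited, for each of 4 libraries, a list of assembled receptor contigs with the cell barcode, the V, J and C gene, the CDR3 and the count of reads and of UMIs behind each contig. UMIs are molecular tags, so that a UMI count is a count of captured molecules. Cell Ranger 6.0 and the mm10 assembly are named per the submitters' processing notes, which do not give the role of each. Every contig in the deposited lists was marked as a cell's, of high confidence, full-length and productive, and 0 contigs were from loci other than TRA and TRB. The 4 expression samples and the heterozygous libraries were not analysed here. Whether doublets were removed before deposit is not given in the sources used here, and no doublet caller was run; cells with 2 TRB contigs were left out of paired cells.

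Groups were taken from the sample labels. A paired cell had 1 or 2 TRA contigs and exactly 1 TRB contig, and the TRA contig with the most UMIs stood for the cell in segment counts. A cell was iNKT-type with any TRA contig of TRAV11 or TRAV11D joined to TRAJ18, MAIT-type with TRAV1 joined to TRAJ33, and of the TRAV10-TRAJ50 type with TRAV10 or TRAV10D joined to TRAJ50. All other paired cells were called outside the invariant classes. A receptor was the V gene, J gene and CDR3 nucleotides of both chains, and a receptor carried by 2 or more cells of a library was counted as expanded. In shares of distinct receptors each receptor took the class of 1 of its cells, while numbers of receptors per class include every receptor with a cell of the class. CDR3 shares were taken over the cells whose TRA contig with the most UMIs was of the class. A combined name for TRBV12-2 and TRBV13-2 was counted as TRBV13-2, since 6983 of its 6987 contigs had the framework 1, CDR1 and CDR2 sequences of TRBV13-2, against 503 contigs with the TRBV13-2 name alone. Coordinates of all 165 segments came from the GENCODE annotation of the mm10 assembly.

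Segments were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, on the number of cells per segment and library. The library size was the number of cells, so that a fold change is that of the share. Segments with 10 or more cells over the libraries tested were kept, p-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. The SE of a log2 fold change was derived from its F statistic. Single values per library were compared with an exact two-sided permutation test of 2 against 2 libraries, which has 6 assignments and a smallest p of 0.333. Expanded shares and receptor numbers were set to equal cell numbers by analytic rarefaction. Shares of single libraries carry exact 95% binomial intervals, and a count of 0 was taken to allow 3 cells. Both cover counting error only, and treat cells that share a receptor as separate draws. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

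Named segments followed a rule set before the data were examined: in each segment table up to 8 per direction with the largest log2 fold change among those called with separated libraries, and up to 6 in the pair table. Lists fixed at the same time were always named. They were iNKT alpha (TRAV11, TRAV11D, TRAJ18), MAIT alpha (TRAV1, TRAJ33), TRAV10 alpha (TRAV10, TRAV10D, TRAJ50), iNKT beta (TRBV13-1, TRBV13-2, TRBV13-3, TRBV29, TRBV1), MAIT beta (TRBV13-1, TRBV13-2, TRBV13-3, TRBV19) and natural Th17 beta (TRBV26). The most frequent alpha CDR3 of each invariant class was named in each library.

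The test was tried on simulated data built from the libraries' own sizes and spread, in 20 draws per table. The changes put in were not offset elsewhere, so library totals and the shares of unchanged genes moved as well. Calls of unchanged genes therefore include such shifts in share and are not a plain false-call rate. The test recovered 57% of 4-fold and 85% of 8-fold changes among TRAV genes over all cells, 73.3% and 91.7% among TRAJ genes and 60% and 90% among TRBV genes. Outside the invariant classes it recovered 54% of 4-fold changes among TRAV, 80% among TRAJ and 85% among TRBV genes. Among TRBV genes within MAIT-type cells it recovered 0% of 4-fold and 35% of 8-fold changes. Of unchanged genes over all cells it called 4.55% of TRAV, 5.44% of TRAJ, 2.5% of TRBV and 7.78% of TRBJ genes. Outside the invariant classes it called 2.76%, 2.21% and 4.44% of unchanged TRAV, TRAJ and TRBV genes. Alternatives were TMM factors, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, each library left out in turn, distinct receptors in place of cells, all called cells, contigs with 3 or more UMIs and every TRA contig. In a fit without 1 library, the lone library of its genotype is assumed to vary like the other genotype. A comparison of non-productive TRA contigs was not run, because the contigs analysed were all productive.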

Results

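Paired T cell receptor sequences were examined in thymocytes sorted as CCR6, CD127 and TCR beta positive. CCR6 is a chemokine receptor and CD127 is the alpha chain of the interleukin-7 receptor. The mice were wild-type or lacked PTEN in T cells, through Cre under the Cd4 promoter acting on a floxed Pten gene. PTEN is a lipid phosphatase that opposes PI3-kinase signalling. There were 4 receptor libraries, 2 per genotype, and the comparison asked how T cell-specific loss of PTEN changes the receptor makeup of this sorted population. Heterozygous libraries named in the study's design and the 4 expression libraries were not analysed here, so the Pten transcript could not be used to check the genotype labels. Wild-type replicates 1 and 2 held 6369 and 6779 called cells, of which 4424 and 4529 had a usable receptor pair. Knockout replicates 1 and 2 held 6978 and 8099 called cells, of which 5698 and 6638 had a usable pair. Total receptor UMIs were 212750 and 225605 in the wild-type libraries and 128761 and 159754 in the knockout libraries. The labels do not say that the libraries came from separate mice, so p-values measure only the spread between these samples. With 2 libraries against 2, an exact two-sided permutation test of a single value has 6 assignments and cannot give a p under 0.333; no single value below could pass a threshold.

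Cells with the receptors of 2 innate-like T cell types made up more of the paired cells in both knockout libraries than in both wild-type libraries. Mucosal-associated invariant T (MAIT) cells recognise microbial metabolites on MR1 through an alpha chain that joins TRAV1 to TRAJ33, and invariant natural killer T (iNKT) cells recognise lipids on CD1d through TRAV11 joined to TRAJ18. MAIT-type cells were 18.9% ± 2.87 (SD, n = 2) of paired wild-type cells and 38.4% ± 4.2 (SD, n = 2) of paired knockout cells, a 2.04-fold higher mean share. iNKT-type cells were 22.6% ± 4.17 (SD, n = 2) of wild-type and 35.7% ± 6.38 (SD, n = 2) of knockout cells, 1.58-fold higher. This difference of 13.1 percentage points was 8.57 without knockout replicate 1. The remaining cells, outside the invariant classes, were 53.5% and 63.5% of the wild-type libraries and 24.4% and 27.2% of the knockout libraries. By library, the MAIT-type share was 20.9% and 16.8% in wild-type replicates 1 and 2, with exact binomial 95% intervals of 19.7 to 22.1 and 15.7 to 17.9. It was 35.4% and 41.4% in knockout replicates 1 and 2, with intervals of 34.2 to 36.7 and 40.2 to 42.6. The iNKT-type share was 25.5% and 19.7% in the wild-type libraries (24.3 to 26.9 and 18.5 to 20.8) and 40.2% and 31.2% in the knockout libraries (38.9 to 41.5 and 30.1 to 32.3). These intervals cover counting error only. Both differences gave an exact permutation p = 0.333, the smallest the design allows. A class could be assigned only to cells with a TRA contig. Cells with TRB only, of unknown class, were 20.6% and 22.1% of called wild-type cells and 10.2% and 8.17% of called knockout cells. The shares are therefore those of paired cells, and unequal TRA recovery could account for part of the differences.

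The picture changed when each distinct receptor, rather than each cell, was counted once. MAIT-type receptors were then 13.3% and 11.1% of distinct receptors in the wild-type libraries against 5.15% and 5.05% in the knockout libraries, the opposite direction. iNKT-type receptors were 23.0% and 15.3% of distinct receptors in the wild-type libraries and 25.7% and 15.4% in the knockout libraries, which overlapped. Receptors with at least 1 MAIT-type cell, some of which had their other cells in another class, numbered 386 and 393 in the wild-type libraries and 67 and 95 in the knockout libraries, although the knockout libraries held more MAIT-type cells (2019 and 2746 against 924 and 762). Cells joining TRAV10 to TRAJ50, the alpha chain of another CD1d-restricted population, were rare: 4 and 1 cells in the wild-type libraries and 1 and 16 in the knockout libraries, or 0.0562% ± 0.0483 against 0.129% ± 0.158 (SD, n = 2 each; exact permutation p = 1). The difference of 0.0730 percentage points was -0.0387 without knockout replicate 2, 0.185 without knockout replicate 1 and 0.0389 without wild-type replicate 2.

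**Figure D1:**
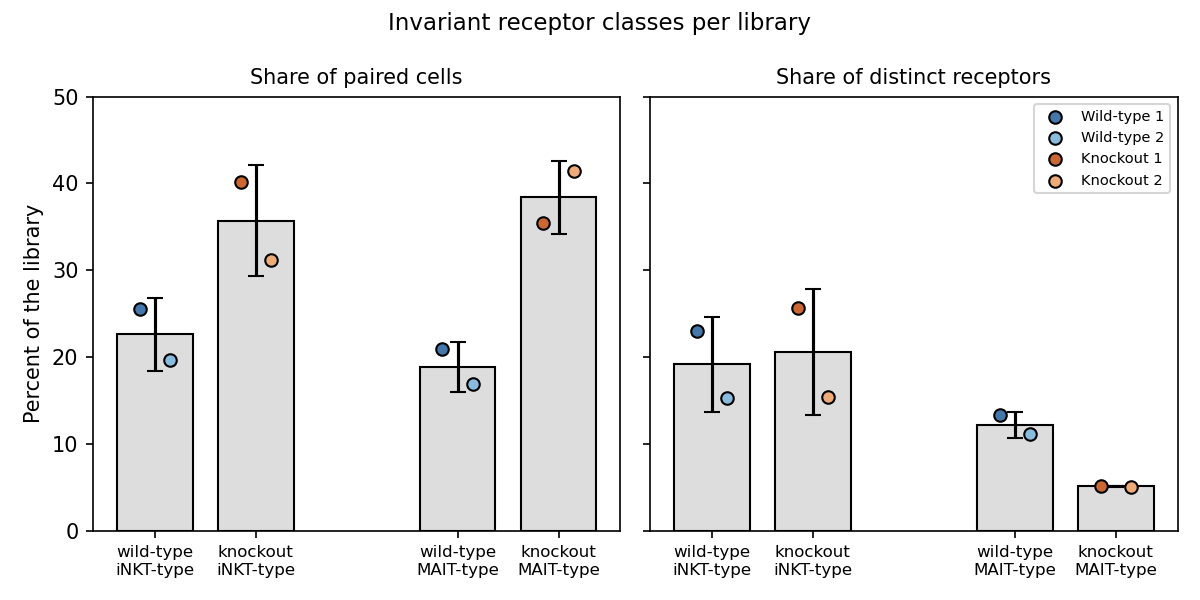
Share of iNKT-type and MAIT-type receptors in each library (percent, y axis), counted per paired cell (left) and per distinct receptor (right). Bars are means of 2 libraries, error bars are SDs and points are libraries; the MAIT-type share is higher in the knockout libraries per cell (35.4% and 41.4% against 20.9% and 16.8%) and lower per distinct receptor (5.15% and 5.05% against 13.3% and 11.1%).

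The alpha chains of the invariant classes carried the same dominant CDR3 in all 4 libraries. The shares given here are over cells whose TRA contig with the most UMIs was of the class, which were 1065, 850, 2252 and 2037 iNKT-type and 878, 724, 2001 and 2700 MAIT-type cells in wild-type replicates 1 and 2 and knockout replicates 1 and 2. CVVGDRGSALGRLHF made up 93.9% and 93.6% of these iNKT-type cells in wild-type replicates 1 and 2 and 95.9% and 90.6% in knockout replicates 1 and 2. Counted over distinct receptors, its share was 93.9% and 93.9% against 83.2% and 87.1%. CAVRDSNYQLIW made up 81.3% and 71.7% of these MAIT-type cells in the wild-type libraries and 88.3% and 88.5% in the knockout libraries. Counted over distinct receptors, its share was instead 77.2% and 71.4% in the wild-type and 68.3% and 60.7% in the knockout libraries. Other CDR3s of the same length varied between libraries of a genotype. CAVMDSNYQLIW was found in 4.33% and 7.73% of wild-type and 4.75% and 0.704% of knockout MAIT-type cells, and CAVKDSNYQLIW in 0.683% and 0% against 0.250% and 8.37%. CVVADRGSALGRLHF was found in 2.07% and 3.76% of wild-type and 2.53% and 7.46% of knockout iNKT-type cells, and over distinct receptors in 2.10% and 2.95% against 9.84% and 3.23%. Among TRAV10-TRAJ50 cells counted in the same way, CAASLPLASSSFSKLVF was carried by 8 of 15 cells in knockout replicate 2, and in the other 3 libraries each CDR3 was seen in a single cell: the first listed were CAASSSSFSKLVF in wild-type replicate 1, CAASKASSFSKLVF in wild-type replicate 2 and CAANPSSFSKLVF in knockout replicate 1.

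Large groups of cells sharing one receptor filled the knockout libraries. At an equal number of 4424 cells, 84.1% and 75.8% of knockout cells shared their receptor with another cell of the library. The wild-type shares were 49.0% and 32.8%. The means were 79.9% ± 5.85 and 40.9% ± 11.5 (SD, n = 2 each, exact permutation p = 0.333). UMIs per cell were not matched. The same number of cells held 1069 and 1371 receptors in the knockout libraries and 2867 and 3441 in the wild-type libraries. Receptors carried by 50 or more cells numbered 20 in each knockout library, where they held 40.0% and 46.8% of paired cells, and 0 in each wild-type library. The largest receptor of knockout replicate 1 was a MAIT-type receptor with TRBV19, TRBJ2-7 and the beta CDR3 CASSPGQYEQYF in 501 cells, 8.79% of the library (exact 95% interval 8.07 to 9.56). In knockout replicate 2 it was a MAIT-type receptor with TRBV13-3, TRBJ2-5 and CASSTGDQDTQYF in 667 cells, 10.0% (9.34 to 10.8), followed by an iNKT-type receptor with TRBV13-1, TRBJ1-2 and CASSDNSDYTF in 392 cells. The largest wild-type receptors held 24 and 22 cells.

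The difference was seen within both invariant classes. At 762 cells per library, 98.7% and 97.1% of knockout MAIT-type cells and 74.7% and 72.3% of wild-type MAIT-type cells shared a receptor. At 890 cells per library, the corresponding iNKT-type values were 88% and 88.2% against 54.1% and 54.9%. Outside the invariant classes the libraries overlapped at 1388 cells each, with 46.2% and 22.2% in the knockout against 26.5% and 10.5% in the wild-type libraries (exact permutation p = 0.667). The difference of 15.7 percentage points there was 3.68 without knockout replicate 1, 27.7 without knockout replicate 2, 23.6 without wild-type replicate 1 and 7.72 without wild-type replicate 2. The 10 largest receptors held 65.9% and 75.7% of knockout MAIT-type cells, 39.9% and 48.9% of knockout iNKT-type cells, and 20.8% and 7.58% of knockout cells outside these classes. In the wild-type libraries they held 14.6% and 11.9%, 11.3% and 12.8%, and 4.82% and 2.96%.

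**Figure D2:**
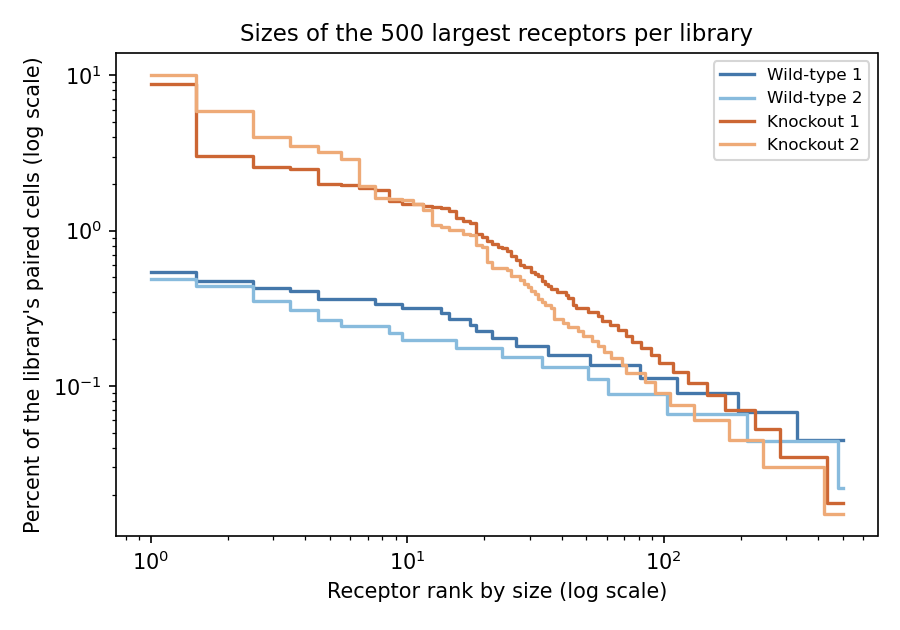
Share of paired cells (percent, log scale) held by each of the 500 largest receptors of a library, ordered by size (rank, log scale), 1 line per library. The largest receptors hold 8.79% and 10.0% of cells in the knockout libraries and 0.542% and 0.486% in the wild-type libraries.

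Counted per alpha V gene over all paired cells, TRAV1 and TRAV11 rose in the knockout libraries and most other TRAV genes fell. TRAV1 (chromosome 14, 52427928 to 52428876 in the mm10 assembly) went from 19.1% ± 2.13 to 38.2% ± 3.83 of cells (SD, n = 2 each), a log2 fold change of 1.0 ± 0.24 (SE; edgeR adjusted p = 0.00435), and TRAV11 (53519303 to 53519859) from 21.6% ± 3.77 to 35.2% ± 6.35, or 0.71 ± 0.25 (adjusted p = 0.0267). The largest falls were in TRAV9D-1, with log2 fold change -3.66 ± 0.68, TRAV5-1 with -3.54 ± 0.61, TRAV5D-4 with -3.43 ± 0.55 and TRAV4-4-DV10 with -3.04 ± 0.53 (SE; edgeR adjusted p from 0.0013 to 0.00143). TRAV6D-5, TRAV14D-3-DV8, TRAV10D and TRAV8-1 fell by 2.89, 2.77, 2.71 and 2.60 on the log2 scale; TRAV6D-5 fell by 5.74 without knockout replicate 2 and TRAV10D by 4.27 without knockout replicate 1. Of 82 TRAV genes tested, 3 rose and 45 fell at an adjusted p under 0.05; the 3 included TRAV7N-4, whose libraries overlapped and which was named only after its values were seen. Because the invariant segments took a larger share of cells, the median TRAV gene had a log2 fold change of -1.56 by cell number and -0.05 with TMM factors, a shift of 1.5. With TMM factors 6 rose and 4 fell, and with DESeq2 4 rose and 0 fell; TRAV1 had 2.52 and TRAV9D-1 -2.21. Without wild-type replicate 1, or without wild-type replicate 2, 0 TRAV genes passed. Counted over distinct receptors TRAV1 fell, by 1.10 on the log2 scale. V genes with near-identical D or N copies, such as TRAV9D-1, are uncertain, since a contig can be assigned to either copy.

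TRAJ33 (chromosome 14, 54185358 to 54185414), the joining segment of MAIT cells, rose from 19.2% ± 2.17 to 38.4% ± 3.83 of cells, a log2 fold change of 1.0 ± 0.18 (SE; edgeR adjusted p = 0.0239). Over distinct receptors it fell instead, by 1.07 on the log2 scale (edgeR adjusted p = 0.106), and 0 TRAJ genes passed. Its log2 fold change over cells was 1.12 without wild-type replicate 1 and 0.89 without wild-type replicate 2. It was 1.10 without knockout replicate 1 and 0.90 without knockout replicate 2. Of these fits, in which 1 genotype had a lone library, TRAJ33 passed only in that without knockout replicate 1. TRAJ18 (54200777 to 54200842), that of iNKT cells, had a log2 fold change of 0.65 ± 0.23 and did not pass (adjusted p = 0.0743). TRAJ43, TRAJ34, TRAJ39, TRAJ13, TRAJ31, TRAJ27, TRAJ17 and TRAJ16 had the largest falls, from -2.31 to -1.98 on the log2 scale. Of 43 TRAJ genes, 1 rose and 18 fell; with TMM factors 2 rose, TRAJ33 and TRAJ18, and 0 fell, with DESeq2 3 rose and 0 fell, and without either wild-type library 0 passed. Of the 2 measured members of the iNKT alpha list (TRAV11 and TRAJ18; TRAV11D was not among the assigned genes) 1 rose over all genes and 2 when adjusted over the list alone. Of the MAIT alpha list (TRAV1 and TRAJ33) 2 rose by either adjustment. Of the TRAV10 list, TRAV10D fell by either adjustment, but was not called with TMM factors, with DESeq2 or over distinct receptors. TRAV10 had -0.94 ± 0.47 and TRAJ50 -0.24 ± 0.31 (-0.07 without knockout replicate 1 and -0.44 without knockout replicate 2). These 2 were above 0 with TMM factors, at 0.60 and 0.95. Over the 204 TRAV-TRAJ pairs tested, 0 passed (edgeR; 36 at an unadjusted p under 0.05; 0 with DESeq2). TRAV1-TRAJ33 had a log2 fold change of 1.08 ± 0.30 (adjusted p = 0.0898) and TRAV11-TRAJ18 of 0.71 ± 0.30 (adjusted p = 0.204). These 2 pairs passed with TMM factors. On simulated data of this size the pair test recovered 0% of 4-fold changes, so it could show little.

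Among beta V genes over all paired cells, TRBV2, TRBV15, TRBV31, TRBV26 and TRBV3 fell in the knockout libraries. Their log2 fold changes were -1.97 ± 0.48, -1.86 ± 0.53, -1.61 ± 0.46, -1.45 ± 0.54 and -1.41 ± 0.45 (SE; edgeR adjusted p from 0.0040 to 0.0449), and these were the 5 of 21 TRBV genes that passed. As for TRAV genes, the larger share of the invariant classes enters these falls. The median TRBV gene had -0.67 by cell number and 0.01 with TMM factors. Outside the invariant classes TRBV2, TRBV15, TRBV31 and TRBV3 had -0.76, -0.70, -0.62 and -0.23 and did not pass. TRBV26 (chromosome 6, 41227505 to 41227993), a segment known from natural IL-17-producing thymocytes, was 1.63% and 2.45% of wild-type and 0.456% and 1.02% of knockout cells. It fell also when adjusted over its list alone, but not outside the invariant classes, where its log2 fold change was -0.74 ± 0.36 (adjusted p = 0.276; -0.37 without knockout replicate 1 and -1.35 without knockout replicate 2). Members of the iNKT beta list did not pass over all cells or over the list alone: TRBV29, TRBV13-3, TRBV13-1, TRBV13-2 and TRBV1 had log2 fold changes of 0.68, 0.57, 0.33, 0.32 and 0.30. All but TRBV29 depended on single knockout libraries: without knockout replicate 1 and without knockout replicate 2, in this order, TRBV13-3 had 1.08 and -0.22, TRBV13-1 0.63 and -0.06, TRBV13-2 0.14 and 0.48 (0.18 without wild-type replicate 2) and TRBV1 -0.09 and 0.61. The MAIT beta list added TRBV19 at 0.26 (-1.01 without knockout replicate 1 and 0.92 without knockout replicate 2) and likewise had 0 members that passed by either adjustment. TRBJ1-3 fell from 4.82% ± 0.141 to 1.61% ± 0.365 and TRBJ1-4 from 5.48% ± 0.0196 to 2.47% ± 0.152 of cells (SD, n = 2 each; edgeR adjusted p = 0.0141 for both), the 2 of 12 TRBJ genes that passed. With TMM factors and with DESeq2 0 TRBV genes passed, and without either wild-type library 0 TRBV and 0 TRBJ genes did. Without knockout replicate 2, 14 TRBV genes passed. The TRBV falls became 1 (TRBV31) and TRBJ falls 0 over distinct receptors.

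Within iNKT-type cells, beta V gene use was led by TRBV13-2 in every library, at 50% and 51.0% of wild-type and 51.0% and 40.7% of knockout cells. TRBV29 was 8.20% ± 0.327 of wild-type and 12.3% ± 0.0886 of knockout iNKT-type cells (SD, n = 2 each), a log2 fold change of 0.59 ± 0.16 that did not pass (edgeR adjusted p = 0.207). TRBV13-1, TRBV1 and TRBV13-3 had log2 fold changes of 0.03, 0.47 and -0.84. TRBV13-1 had 0.42 without knockout replicate 1 and -0.49 without knockout replicate 2, TRBV1 0.11 and 0.78, and TRBV13-3 -0.52 without wild-type replicate 1. None of 10 TRBV genes passed (edgeR; 1 at an unadjusted p under 0.05; 0 with DESeq2), and 0 of the iNKT beta list passed when adjusted over the list alone. Over distinct receptors TRBV29 rose by 0.73 ± 0.22 and TRBV13-1 fell by 0.62 on the log2 scale (edgeR adjusted p = 0.0204 for both). TRBV13-1 was 33.0% of iNKT-type cells in knockout replicate 2, where 1 receptor held 392 of 683 such cells, and 17.5% in knockout replicate 1. Without knockout replicate 1, or without knockout replicate 2, 2 genes passed. In simulated cell counts of this class 17.1% of unchanged TRBV genes were called, a rate that includes shifts in share made by the simulated changes. It was not computed for distinct receptors or with a library left out. Genes of this class were called only in those counts, so the calls are weakly held.

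Within MAIT-type cells TRBV19 and TRBV13-3 use differed more between the knockout libraries than between the genotype means. TRBV19 was 18.1% and 19.0% of wild-type cells but 37.8% and 4.77% of knockout cells, and TRBV13-3 was 35.2% and 29.5% of wild-type but 21.3% and 55.6% of knockout cells. TRBV13-2 was 25.6% and 23.9% of wild-type and 26.8% and 24.7% of knockout cells, and TRBV13-1 0.541% and 0.787% against 0% and 4.73%. TRBV29, TRBV31 and TRBV17 were found in 1.79% ± 0.998, 1.14% ± 0.239 and 0.861% ± 0.453 of wild-type MAIT-type cells (SD, n = 2). They were found in 0 of 2019 and 0 of 2746 knockout cells. If cells were separate draws, 0 would allow 3 cells per library, or shares of up to 0.149% and 0.109%. The wild-type means were 13.9-fold, 8.87-fold and 6.68-fold the mean of these limits. Knockout MAIT-type cells came from 67 and 95 receptors, however, and the 10 largest held 65.9% and 75.7% of them. The limits are therefore too low, and the folds are not lower bounds. These were the 3 of 14 genes that passed (edgeR adjusted p = 0.0493, 0.0312 and 0.0312). The count was 0 without the filter on low counts, over distinct receptors and without either wild-type library, 8 without knockout replicate 1 and 10 without knockout replicate 2. Of the MAIT beta list 0 passed over all genes or over the list alone. The difference of the knockout effect on TRBV use between iNKT-type cells and cells outside the invariant classes passed for 0 of 21 genes (edgeR; 2 at an unadjusted p under 0.05; 0 with DESeq2).

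Outside the invariant classes, joining segments at the 5′ end of the TRAJ cluster were used more in the knockout libraries and those in its middle less. TRAJ61 to TRAJ42 were joined in 27.9% and 27.4% of wild-type and 38.3% and 40.3% of knockout cells, and TRAJ41 to TRAJ22 in 46.5% and 48.3% against 31.3% and 37.4%. The mean TRAJ number, counted from the 3′ end, was 31.3 ± 0.00555 in the wild-type and 33.1 ± 1.06 in the knockout libraries (SD, n = 2 each; exact permutation p = 0.333), a difference of 1.80 that was 1.06 without knockout replicate 2. Over distinct receptors the 5′ share stayed apart, at 30.1% and 28.7% against 34.9% and 45.3%, while the mean number overlapped, at 32.4 and 31.8 against 31.7 and 36.1. TRAJ21 to TRAJ1, at the 3′ end, overlapped, with 25.5% and 24.4% against 30.5% and 22.3%. The TRAV genes nearest the TRAJ cluster were used by 41.7% and 41.2% of wild-type and 44.2% and 49.6% of knockout cells, and overlapped over distinct receptors. The middle TRAV group (28.0% and 30.6% against 23.3% and 28.7%) and the distal group (30.3% and 28.3% against 32.5% and 21.7%) overlapped, although over distinct receptors the middle group was lower in both knockout libraries, at 26.6% and 25.7% against 29.1% and 31.6%.

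**Figure D3:**
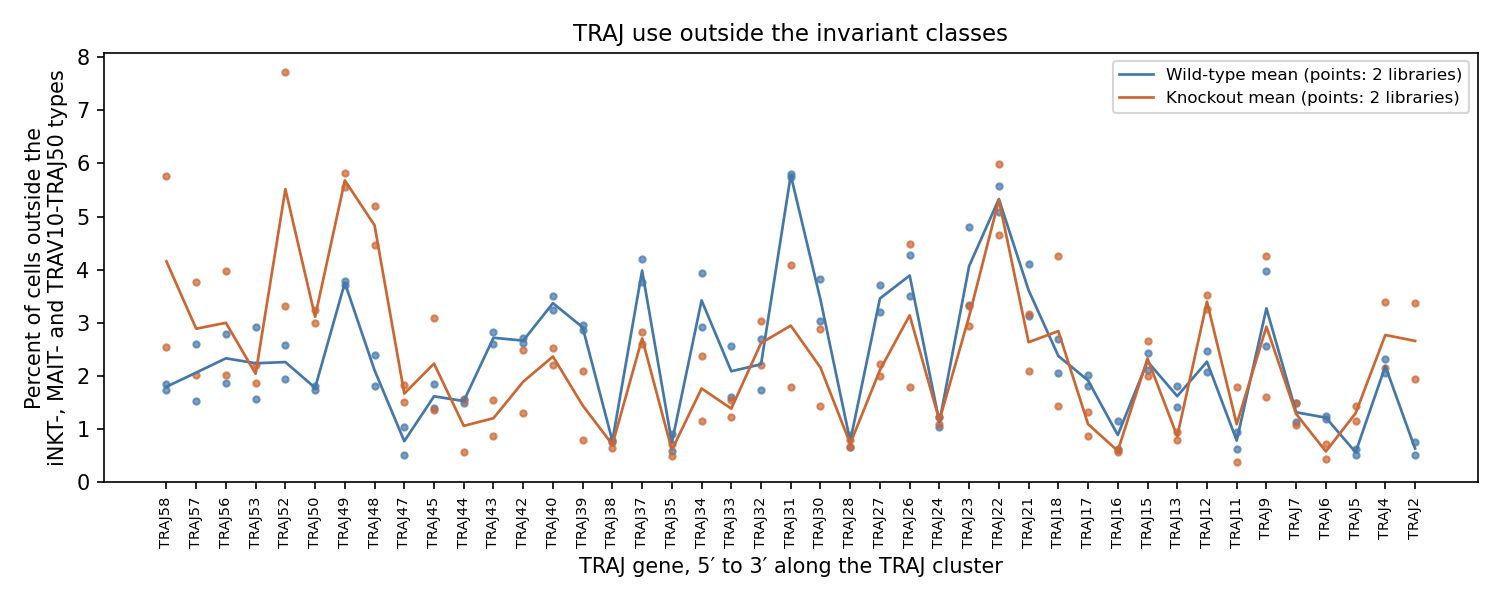
Share of cells outside the invariant classes (percent, y axis) that use each TRAJ gene, ordered 5′ to 3′ along the cluster (x axis). Lines are means of the 2 libraries per genotype and points are libraries; TRAJ49 lies at 5.55% and 5.81% in the knockout and 3.72% and 3.79% in the wild-type libraries, and TRAJ31 at 1.80% and 4.10% against 5.75% and 5.81%.

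Gene by gene, no segment outside the invariant classes passed when cells were counted. The counts were 0 of 82 TRAV, 0 of 43 TRAJ and 0 of 21 TRBV genes (edgeR; 23, 10 and 3 at an unadjusted p under 0.05; 2, 1 and 0 with DESeq2). When distinct receptors were counted, 2 TRAV genes rose and 6 fell. TRAV16 rose by 1.73 ± 0.28 and TRAV16N by 1.20 ± 0.24, and TRAV5-1, TRAV9D-1, TRAV5D-4, TRAV4-4-DV10, TRAV8-1 and TRAV14N-3 fell, by 2.15 to 1.17 on the log2 scale (edgeR adjusted p from 0.0387 to 0.0499). In the same count TRAJ2, TRAJ47 and TRAJ49 rose (1.62 ± 0.42, 1.31 ± 0.37 and 0.66 ± 0.23) and TRAJ31 fell by 1.08, and TRBV29, TRBV14, TRBV12-2 and TRBV12-1 rose while TRBV1 and TRBV31 fell. These genes were named after their values were seen. TRAJ2, the TRAJ gene with the lowest adjusted p when cells were counted (0.104), was 0.507% and 0.765% of wild-type and 1.95% and 3.38% of knockout cells, and passed with DESeq2, with TMM factors and without either knockout library. It did not pass without either wild-type library, with all called cells or with 3 or more UMIs, and 42 of its 61 cells in knockout replicate 2 carried 1 receptor with TRAV7N-4. Without knockout replicate 1, 2 TRAJ and 8 TRBV genes passed, and without knockout replicate 2, 7 and 3.

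Counted over cells, CDR3 loops outside the invariant classes were longer on average in the knockout libraries. The mean TRA CDR3 length was 13.6 ± 0.0896 residues in the wild-type and 14.1 ± 0.145 in the knockout libraries, and the mean TRB CDR3 length 14 ± 0.0923 and 14.2 ± 0.000688 (SD, n = 2 each; exact permutation p = 0.333 for both). The 10 largest receptors held 20.8% and 7.58% of these knockout cells, against 4.82% and 2.96% of wild-type cells. Large receptors therefore weigh more on the knockout means. Within the classes the mean TRB CDR3 length over cells was lower in both knockout libraries, at 13.8 ± 0.606 against 14.4 ± 0.0527 residues in iNKT-type cells and 14.1 ± 0.303 against 14.6 ± 0.135 in MAIT-type cells. The iNKT-type difference of -0.599 residues rested mostly on knockout replicate 2: it was -0.171 without that library, -1.03 without knockout replicate 1 and -0.147 over distinct receptors. The MAIT-type difference of -0.462 was -0.247 without knockout replicate 1, and over distinct receptors the libraries overlapped. The MAIT-type difference went the other way, to 0.0776 residues longer, when the largest receptor of each library was left out. A hydrophobic residue at both positions 6 and 7 of the TRB CDR3 was found in 1.65% and 1.81% of wild-type and 1.51% and 1.94% of knockout cells outside the classes. Over all paired cells it was found in 1.36% and 1.39% against 0.597% and 0.648%. In MAIT-type cells it was found in 2.06% and 0.656% against 0% and 0% (exact permutation p = 0.333 for both comparisons). There 0 would allow up to 0.149% and 0.109% if cells were separate draws, although many shared a receptor. Over distinct receptors of all cells the libraries overlapped, at 1.29% and 1.51% against 1.43% and 1.44%. In iNKT-type cells it was 0.177% and 0.674% against 0.568% and 0.387%. An inner cysteine was found in 6.26% and 6.29% of wild-type and 15.7% and 3.87% of knockout cells outside the classes, which overlapped, as they did over all cells (6.13% and 6.36% against 9.44% and 5.86%) and within the iNKT-type and MAIT-type classes. Over distinct receptors it was lower in both knockout libraries, at 4.01% and 2.62% against 6.52% and 6.19% outside the classes and 5.70% and 3.40% against 6.87% and 6.41% overall (exact permutation p = 0.333 for both), and overlapped within the 2 classes. This measure largely restated TRBV1 use, since the CDR3s of the leading TRBV1 receptors begin with CTCS. Outside the classes TRBV1 was used by 6.21% and 6.15% of wild-type and 15.6% and 3.65% of knockout cells. Over distinct receptors TRBV1 fell there by 1.10 on the log2 scale.

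Few receptors were shared between libraries. At an equal number of 1233 TRB receptors, 0.654% were shared by amino acid sequence between the 2 wild-type libraries and 0.705% between the 2 knockout libraries. Knockout replicate 1 shared 1.33% and 1.25% with wild-type replicates 1 and 2, and knockout replicate 2 shared 0.503% and 0.446% with them. The mean over pairs of different genotype was 0.881% and over pairs of the same genotype 0.679%; without knockout replicate 1 these were 0.474% and 0.654%.

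Chain recovery differed between the genotypes by more than between replicates. A usable pair was found in 68.1% ± 1.88 of called wild-type and 81.8% ± 0.215 of called knockout cells (SD, n = 2 each; exact permutation p = 0.333). Cells with TRB only were 20.6% and 22.1% of wild-type and 10.2% and 8.17% of knockout cells, and cells with TRA only 1.05% and 0.929% against 5.78% and 3.51%. A second TRA was found in 8.81% and 9.65% against 3.57% and 4.28%, and a second TRB in 8.87% and 10.2% against 2.35% and 6.36%. The median TRA contig had 6 UMIs in every library, whereas the median TRB contig had 21 and 21 UMIs in the wild-type and 10 and 11 in the knockout libraries. Reads per UMI were 63.5 and 84.1 in the wild-type and 158.7 and 155.5 in the knockout libraries.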

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

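The alternatives with V names as deposited, without the largest receptor, with cells over the median UMIs and without large knockout replicate 1 receptors in the wild-type libraries were chosen after the results were seen. Over 949 alternative values, 684 stayed on their side of the threshold or within the spread, 146 lost a call, 17 gained one, 91 moved and 11 reversed where a value was called or the genotypes did not overlap. A further 28 changed sign with neither, and are counted among those that moved (26) or stayed (2). With TMM factors the counts of called segments were 2 pairs, 10 TRAV, 2 TRAJ and 0 TRBV genes over all cells and 3 TRAJ genes outside the classes. With DESeq2 they were 4 TRAV, 3 TRAJ, 0 TRBV and 4 TRBJ genes over all cells, and 2 TRAV and 1 TRAJ genes outside the classes. Over distinct receptors they were 16 TRAV, 0 TRAJ, 1 TRBV and 0 TRBJ genes over all cells, 8 TRAV, 4 TRAJ and 6 TRBV genes outside the classes, 2 TRBV genes in iNKT-type and 0 in MAIT-type cells. With all called cells they were 3 TRBV genes over all cells, 8 TRAV genes outside the classes and 0 TRBV genes in MAIT-type cells. With every TRA contig, 4 TRAV and 1 TRAJ genes were called outside the classes. The TRBV count in MAIT-type cells was 0 also without the filter, with 3 or more UMIs and with V names as deposited. Leaving out each library in turn gave 0 to 54 TRAV, 0 to 23 TRAJ, 0 to 14 TRBV and 0 to 3 TRBJ genes over all cells, 0 to 7 TRAJ and 0 to 8 TRBV genes outside the classes, 0 to 2 TRBV genes in iNKT-type and 0 to 10 in MAIT-type cells. Fewer libraries entered these fits.

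Over distinct receptors the iNKT-type difference was 1.41 percentage points and the MAIT-type difference -7.08. The MAIT-type difference was 13.3 without the largest receptor of each library and 4.73 in cells over the median UMIs, where the libraries overlapped, at 19.0% and 26.0% in the knockout against 19.1% and 16.5% in the wild-type. That filter adds TRA and TRB UMIs, and MAIT-type cells had median TRB UMIs of 8 and 9 in the knockout and 24 and 24 in the wild-type libraries, so by construction it removes knockout MAIT-type cells most and says little of their share. The TRB CDR3 length difference in MAIT-type cells reversed to 0.0776 residues without the largest receptor. Log2 fold changes reversed over distinct receptors for TRAV1 (-1.10), TRAJ33 (-1.07), TRBV3 (0.063) and, in iNKT-type cells, TRBV13-1 (-0.62). Leaving out knockout replicate 2 gave the lowest value and knockout replicate 1 the highest for TRBV13-1 in iNKT-type cells (-0.49 to 0.42), TRBV13-1 in MAIT-type cells (-6.04 to 2.83) and TRBV13-3 in MAIT-type cells (-0.60 to 0.78). The order was the opposite for TRBV19 over all cells (-1.01 to 0.92) and in MAIT-type cells (-1.96 to 1.03). Distinct receptors weigh each receptor once by construction; elsewhere the cause was not tested.

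The labels give both genotypes replicates 1 and 2 but do not say that a number marks a shared mouse, litter or day. Deviations of same-numbered libraries outside the classes had correlations across genes of 0.117 for TRAV, 0.213 for TRAJ and 0.206 for TRBV genes. With the replicate block, 2 pairs, 47 TRAV, 15 TRAJ, 5 TRBV and 0 TRBJ genes were called over all cells (TRAJ33 was not, at an edgeR adjusted p of 0.0505), 0 TRAV, 1 TRAJ and 0 TRBV genes outside the classes, and 0 TRBV genes in iNKT-type and 0 in MAIT-type cells. The comparison of non-productive TRA contigs was not run, because all contigs analysed were productive.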

Other observations

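All tests in this part except those of expanded shares in cells over the median UMIs and of chains of the other class were chosen after the result was seen. Cells with both an iNKT-type and a MAIT-type alpha chain numbered 3 and 3 in the wild-type and 0 and 0 in the knockout libraries. Among cells with the TRB chain of a large MAIT-type receptor, 0 of 1716 in knockout replicate 1 and 0 of 2435 in knockout replicate 2 carried an iNKT-type alpha chain. Among cells with the TRB chain of a large iNKT-type receptor, 0 of 1104 and 0 of 1148 carried a MAIT-type alpha chain. This was planned as a test of free receptor RNA whose chains pair at random, which by the bound set before would be argued against. That bound did not allow for removal of mixed barcodes before deposit, about which nothing is given. 0 of 6369, 6779, 6978 and 8099 barcodes held 3 or more TRA or TRB contigs. The 19 and 23 knockout barcodes with TRB chains of 2 large receptors were 1 repeated pair in each library. Some mixed barcodes may remain, such as the 3 and 3 wild-type cells with both alpha chains. The test therefore cannot decide, a reservation added after its result was seen. Cells with 2 TRB contigs, a possible sign of droplets with 2 cells, were also examined as an explanation of large receptors. They were fewer in the knockout libraries, at 2.35% and 6.36% against 8.87% and 10.2%. Median TRB UMIs were 10 and 11 against 21 and 21, so a second TRB could be missed more often there. The count therefore decides nothing about large receptors. TRBC2 was the constant gene of 68.0% and 65.6% of wild-type and 75.1% and 70.6% of knockout TRB contigs.

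Receptors carried by 20 or more cells of knockout replicate 1 were found in both wild-type libraries. Of 44 such receptors, 16 were found in 24 cells of wild-type replicate 1 and 19 in 26 cells of wild-type replicate 2, with 0 in knockout replicate 2. Reads assigned to the wrong library are argued against, as 0 of the 50 wild-type cells shared a barcode with a cell of knockout replicate 1. Independent generation of the same receptors is argued against, as 0 of 37 large receptors of knockout replicate 2 were found in the wild-type libraries. Cells of knockout replicate 1 in the wild-type libraries remain a candidate explanation: draws in proportion to receptor size gave 12 to 20 and 13 to 21 receptors, and the cells' median TRB UMIs of 12.5 and 11 lay nearer to 9 in knockout replicate 1 than to 22 in the wild-type libraries.

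TRB UMIs per cell were lower in the knockout libraries. Less sequencing is argued against, since the lowest knockout library had 155.5 reads per UMI. A loss of TRB molecules shared by every cell of a library is argued against as the whole cause. Over 5 TRBV genes, the knockout over wild-type ratio of median TRB UMIs was higher outside the classes than in MAIT-type cells. The excess was 0.193 and 0.336 in replicates 1 and 2. Outside the classes the median ratio was itself 0.610 and 0.696, so such a loss stays open as part of the cause. Some knockout MAIT-type medians rest on few receptors, which limits this comparison. In knockout replicate 1 a single receptor held 501 of 764 MAIT-type TRBV19 cells, and another 146 of 226 TRBV5 cells. The ratios also paired same-numbered libraries, although the labels do not say that a number marks a shared origin. A genotype effect on TRB transcripts stays open as a hypothesis: medians were lower in both knockout libraries in 3 of 3 classes, but it was drawn from these values, which cannot also verify it. No batch is named in the labels.

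Large receptors and a larger MAIT-type share marked the knockout libraries. Free receptor RNA counted as cells stays open as a source of large receptors. Among cells over their library's median UMIs the lowest knockout expanded share was 59.2%, 18.0 percentage points over the highest wild-type share. By the bound set before, this would argue against it. The cut was each library's own median, however, so cells of every library pass whatever their source. The test therefore cannot decide. That cut lowered the knockout expanded shares, at the same 2152 cells, from 79.3% and 71.3% to 71.7% and 59.2%. It also lowered the knockout share of MAIT-type cells, the most expanded class, from 35.4% and 41.4% to 19.0% and 26.0%. The fall in expanded shares therefore cannot be told from a change in class mix. Cells of knockout receptors with 20 or more cells also had fewer UMIs than cells of single-cell receptors. Their medians were 5 and 5 against 8 and 8 for TRA and 9 and 10 against 15 and 17 for TRB. The 2 sets were not matched for class, however, and most cells of the large receptors were MAIT-type or iNKT-type. Knockout medians by class were 5 and 5 TRA UMIs in MAIT-type, 7 and 7 in iNKT-type and 8 and 8 in other cells. For TRB they were 8 and 9, 10 and 10, and 15 and 15. The gap therefore cannot tell free RNA from a difference in class. The wild-type libraries each held only 2 receptors of 20 or more cells, with 45 and 42 cells. There TRB medians were higher, at 28 and 29.5 against 21 and 22, and TRA medians were 4 and 6 against 7 and 6. Free receptor RNA whose chains pair at random stays open. Of cells with a large MAIT-type TRB chain 0% carried an iNKT-type alpha chain, but mixed barcodes may have been removed before deposit. Free receptor RNA counted as MAIT-type cells stays open, since the chains point in opposite directions: median TRA UMIs were 5 in each knockout library against 4 and 3 in the wild-type libraries, and median TRB UMIs 8 and 9 against 24 and 24. A genotype effect on expansion of single receptors is a hypothesis that stays open. The expanded share of both knockout libraries lay above both wild-type libraries in 2 of 3 classes and overlapped outside the invariant classes, where the largest receptor was still larger, at 6.05% and 2.32% against 0.761% and 0.695% of cells. It too was drawn from these values, and free receptor RNA as a source was not excluded.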
